A study of Mus musculus with 24 samples.

How the data were processed

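The series holds 24 bulk RNA-seq libraries of mouse microglia, the resident macrophages of the brain, from animals with 2, 1 or 0 intact copies of 3110043O21Rik, the mouse counterpart of C9orf72. Wild-type, heterozygous and homozygous knockout animals were sampled at 3 and 17 months of age, with 4 animals in each of the 6 groups, all labelled C57BL/6J. Per the labels' protocols, brains were freed of meninges and dissociated with papain, myelin was taken out with magnetic beads, and CD11b-positive cells were collected with magnetic beads. Polyadenylated RNA was made into stranded libraries and read from a single end on a NextSeq instrument, per the labels' protocols. The labels do not say how the allele was made or which part of the gene it lacks.

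The authors deposited 2 tables for each age. In the TPM tables, the authors gave TPM (transcripts per M, with M for mega) summed to 20636 genes per table. The deposited TPM columns summed to between 78.9% and 90.7% of the total that the unit implies, so part of each library lies in transcripts that the tables do not list. In the RPKM tables, the authors gave reads per kilobase and M alignments (RPKM) for 18721 genes at 3 months and 19210 at 17 months, with the number of alignments of each library. Per the submitters' processing notes, TopHat2 2.1.1, Partek 7.17.0918, Salmon 0.8.2 and DESeq2 were used with mm10. The notes as held here do not tie a tool to a table and name no annotation. No table holds counts, so no count model was used.

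Table columns are headed by an animal number, per the file headers. The RPKM headers pair each number with a genotype, and those pairs put the TPM columns into groups. The headers of the 17-month RPKM table call 4 animals hemi, and these were taken as the heterozygous group. The animal numbers could not be tied to the replicate numbers of the labels. Each group's columns were therefore treated as replicates without pairing, and per-sample labels such as RNA input could not be used. Within each age, every animal's TPM profile correlated best with its own RPKM profile among the 12 animals (deviations from gene means, r from 0.852 to 0.962 at 3 months and from 0.670 to 0.966 at 17 months). No library looked like a copy of another, since the smallest SD of the log2 difference between 2 animals over genes was 0.176 at 3 months and 0.240 at 17 months. The animals' sex is not labelled and was read from the TPM sum of 4 Y-linked genes, with a limit of 5.

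All tests were run on log2(TPM + 1) in R 4.3.3 with limma 3.58.1. Genes with a mean of at least 1 TPM over the 12 animals of an age were kept, which left 11587 genes at 3 months and 11792 at 17 months. Fold changes on this scale understate the change of genes near 1 TPM. The 12 animals of an age entered a single linear model with a mean per genotype, so the genotypes shared an estimate of the spread. Moderated tests used a trend with expression, were two-sided and were adjusted by Benjamini-Hochberg over all genes kept, and a gene was called at an adjusted p under 0.05. The ages stand in separate tables, so they were not tested against each other directly. The difference between the within-age genotype effects was tested over all 24 libraries and 11436 genes. The targeted gene was tested by an exact two-sided permutation test of the difference of mean TPM over 70 assignments, whose smallest possible p is 0.0286.

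A set of 34 gene lists was fixed. They cover microglial states (homeostatic, disease-associated), type I interferon response, MHC class I and class II presentation, inflammatory cytokines and NF-kB targets, complement and its receptors, phagocytic and scavenger receptors, lysosome, autophagy, endosome and small GTPases, mTORC1 and nutrient sensing, cholesterol synthesis, lipid efflux and storage, glycolysis, nuclear-encoded oxidative phosphorylation, cytosolic ribosomal proteins, cell cycle, immediate early and dissociation-associated genes, unfolded protein and integrated stress response, and cGAS-STING and nucleic acid sensing. Other lists hold markers of cells that a CD11b sort can carry along, namely border-associated macrophages, monocytes, neutrophils, T and NK cells, B and plasma cells, astrocytes, oligodendrocytes and their precursors, neurons, endothelial and mural cells, erythrocytes, and choroid plexus and ependyma. A list of mitochondrial transcripts was meant to show RNA quality, but the TPM tables hold 0 such genes and it was not tested. Lists with at least 5 genes kept were tested with limma's camera, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. That gave 30 lists at 3 months and 32 at 17 months, and the list of oligodendrocyte precursors stayed under that size at both ages. Some genes stand in more than 1 list, as Nr4a1 does. The camera test compares a list with all other genes, so its direction can differ from the sign of the list's own mean.

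The lists, the tests, the other settings to be tried and the rule for the genes named in the text were fixed before the data were examined. The rule names the targeted gene, its protein partners Smcr8 and Wdr41, and Tmem119, P2ry12 and Cx3cr1 in every comparison. It adds, for each mutant against wild type, up to 10 called genes with the largest rise and 10 with the largest fall among those whose 4 mutant values all lay on the same side of the 4 wild-type values. It further adds up to 4 called members of each list past its test, or the 2 uncalled members with the largest change in the list's direction, and the 5 genes with the smallest adjusted p for the difference between ages. A few genes outside the rule are named and marked as chosen after their values were seen. Gene positions come from the GENCODE annotation of mm10, in which 11552 of the 11587 genes kept at 3 months and 11755 of the 11792 at 17 months were found by name.

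Precision was set by the 4 animals per group and by depth, from 16.7 to 46.4 M alignments. The steps were tested on simulated values for the homozygous against wild-type comparison, with 67 genes changed by 0.5 on the log2 scale, 67 by 1 and 66 by 2. At 3 months 64.2%, 89.6% and 95.5% of those changes were recovered, and 9 of 175 calls were false. At 17 months 22.4%, 70.1% and 98.5% were recovered, and 3 of 130 calls were false. In the simulated heterozygous comparison, without changes, limma called 0 genes. A ribosomal list shifted in a further simulation was called at both ages, at 3 months beside 1 unshifted list. Regrouped real animals called up to 22 lists, so the rates hold for simulated values only.

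The other settings, fixed at the same time, were a pseudocount of 0.1, no filter on low values, a minimum mean of 5 TPM, the RPKM tables, quantile normalization, centring each library on its median, a fit on only the 2 groups compared, limma's array weights, a sex covariate, each animal left out in turn, and camera with an estimated correlation. Fits on females only or males only, and the leave-one-out values of the correlation between both mutants' fold changes, were added after seeing the data. For the comparisons that share the wild-type libraries, 100 simulations of unchanged groups and 6 splits of the wild types were run. Simulated counts of shared genes, for lists of the observed sizes and with each gene drawn independently, were added after the calls were seen. No per-sample column was left out.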

Results

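Microglia were profiled in wild-type, heterozygous and homozygous 3110043O21Rik knockout mice at 3 and 17 months, with 4 animals per genotype and age. Single animals are named by genotype (WT, HET, HOM) and the animal number of the tables. The gene is the mouse counterpart of C9orf72, whose protein acts with Smcr8 and Wdr41 in membrane traffic and lysosome biology. At 3 months the libraries held 24.9 ± 2.71 M alignments in wild types (SD, n = 4), 27.9 ± 1.28 in heterozygotes and 31.6 ± 1.48 in homozygotes. At 17 months they held 30.4 ± 9.15 M in wild types, 34.1 ± 3.33 in heterozygotes and 42.4 ± 2.67 in homozygotes. Homozygous libraries were deeper than wild-type and heterozygous ones at both ages. Each exact two-sided permutation test gave p = 0.0286, 0.0429 after Benjamini-Hochberg adjustment over the 6 comparisons. By Y-linked transcripts, 1 wild type, 4 heterozygotes and 2 homozygotes were male at 3 months. At 17 months 1 wild type, 0 heterozygotes and 3 homozygotes were male, so sex was not balanced over the genotypes at either age.

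The first question was how far the targeted transcript was reduced. At 3 months 3110043O21Rik (chromosome 4, 35191285 to 35226175, minus strand, mm10) stood at 22.8 ± 2.23 TPM in wild types (SD, n = 4). It stood at 9.73 ± 1.75 TPM in heterozygotes, 42.6% of the wild-type mean, and at 0.139 ± 0.0918 TPM in homozygotes, 0.610% of it. At 17 months it stood at 14.9 ± 1.48 TPM in wild types, 7.20 ± 1.53 in heterozygotes (48.5%) and 0.0360 ± 0.0158 in homozygotes (0.243%). Each mutant group differed from its wild types with p = 0.0286 (exact permutation test, two-sided), the smallest p that 4 against 4 animals can give. Transcripts of the partners Smcr8 (chromosome 11) and Wdr41 (chromosome 13) were not called in any comparison. Smcr8 was at 28.3 ± 2.62 TPM in wild types and 24.3 ± 1.47 in homozygotes at 3 months (log2 change -0.21, adjusted p = 0.435), and at 14.4 ± 2.51 and 17.0 ± 1.80 TPM at 17 months (0.24, adjusted p = 0.466). Wdr41 was at 35.7 ± 2.13 and 32.9 ± 3.89 TPM at 3 months, and at 25.6 ± 2.70 and 25.6 ± 0.519 TPM at 17 months. Within 10 megabases of the targeted gene, 76 genes were tested at 3 months and 81 at 17 months. None of them was called by limma against wild type, with from 9 to 17 at an unadjusted p under 0.05. Hrct1 and Reck, which lie in that interval and are named after their values were seen, were called between homozygotes and heterozygotes at 17 months (Fisher's exact test against genes farther away, two-sided, p = 0.662).

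**Figure D1:**
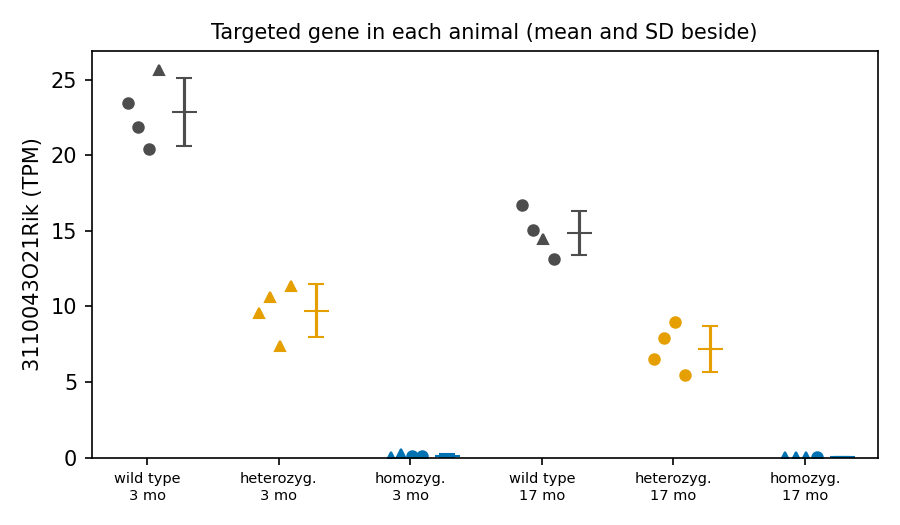
TPM of 3110043O21Rik in each animal, by genotype and age, with circles for females and triangles for males and with the mean and SD of the 4 animals beside them. Group means fall from 22.8 to 9.73 and 0.139 TPM at 3 months and from 14.9 to 7.20 and 0.0360 TPM at 17 months.

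The homozygous against wild-type comparison at 3 months asked what loss of both copies does in young microglia. Few single genes were called, and the ribosomal protein list had the smallest p of the lists. Rps15a and Rpl39, parts of the small and the large ribosomal subunit, rose from 54.9 ± 2.33 to 70.2 ± 3.17 TPM and from 1386 ± 58.2 to 1761 ± 88.8 TPM (SD, n = 4, log2 changes 0.35 and 0.34, adjusted p = 0.0441 each). Tlr12, an endosomal receptor that senses microbial profilin, fell from 40.8 ± 1.59 to 29.7 ± 0.680 TPM (log2 change -0.44, SE 0.050, adjusted p = 0.00629). Rab11fip5, which binds Rab11 on recycling endosomes, fell from 80.3 ± 2.90 to 64.9 ± 1.62 TPM (adjusted p = 0.0441). In all, limma called 7 of 11587 genes, 2 higher and 5 lower, and in each the 4 homozygotes lay apart from the 4 wild types. The other lower genes were the targeted gene, Rpn2, a subunit of oligosaccharyltransferase (log2 change -1.22, adjusted p = 0.0441), and the predicted gene Gm3435 (-0.93, adjusted p = 0.0441). In the RPKM tables Rpn2 differed by -0.0057 (adjusted p = 0.981).

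All 50 members of the cytosolic ribosomal protein list, which does not hold Rps15a or Rpl39, had positive changes at 3 months, with a mean log2 change of 0.22 and an SD of 0.059 over members. The list rose (adjusted p = 7.24e-52, 0.142 with an estimated correlation). Of its members 0 were called over all genes and 42 when adjusted over the list alone. Rps24 stood at 1426 ± 79.3 against 1134 ± 36.0 TPM and Rps28 at 531 ± 40.5 against 421 ± 32.8 TPM. The disease-associated microglia list, made of genes of lipid handling and phagocytosis that microglia express around lesions, rose by a mean of 0.15 (adjusted p = 2.59e-07, 0.142 with an estimated correlation). It had 0 members called over all genes and 3 adjusted over the list alone, and Gpnmb stood at 9.38 ± 3.35 against 2.44 ± 0.871 TPM (adjusted p = 0.0512). The MHC class II list rose by 0.21 (adjusted p = 1.77e-06, 0.142 with an estimated correlation), with 4 of 12 members called when adjusted over the list alone and H2-Aa at 854 ± 242 against 526 ± 52.4 TPM. The MHC class I list rose by 0.090 (adjusted p = 6.81e-06, 0.142 with an estimated correlation), with 0 members called either way. Inflammatory cytokines and NF-kB targets rose by 0.19 (adjusted p = 4.07e-07, 0.255 with an estimated correlation), with 3 members up and 1 down when adjusted over the list alone.

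Smaller shifts were called at 3 months for oxidative phosphorylation (mean 0.026, adjusted p = 2.69e-05, 0.577 with an estimated correlation) and cell cycle (0.039, adjusted p = 5.42e-04, 0.329 with an estimated correlation). Immediate early and dissociation-associated genes rose by 0.14 (adjusted p = 2.07e-07, 0.391 with an estimated correlation), and HOM-8285 stood apart with a score of -0.41 where the other 3 lay from 0.315 to 0.334. Phagocytic and scavenger receptors were called up with a mean of 0.014 and a median of -0.044 (adjusted p = 0.0281, 0.255 with an estimated correlation). The median change of all genes was -0.10, so a list near 0 lay above other genes, and with each library centred on its median that value was 0.014. Markers of blood cells were higher in homozygotes, namely neutrophils by 0.98 (adjusted p = 6.29e-12, 0.216 with an estimated correlation, 9 of 16 called over the list alone) and monocytes by 0.59 (adjusted p = 2.24e-10, 0.142 with an estimated correlation, 4 of 14 over the list alone). T and NK cell markers were higher by 0.23 (adjusted p = 9.20e-04, 0.255 with an estimated correlation) and border-associated macrophage markers by 0.15 (adjusted p = 8.29e-06, 0.255 with an estimated correlation). Markers of endothelial and mural cells were lower, with a mean of -1.06 (adjusted p = 1.71e-04, 0.574 with an estimated correlation, 11 of 14 over the list alone). Astrocyte markers were lower, with a mean of -0.50 (adjusted p = 0.00970, 0.592 with an estimated correlation). Tmem119, P2ry12 and Cx3cr1, which mark resident microglia, were not called, and Cx3cr1 stood at 3228 ± 46.8 against 3523 ± 236 TPM (adjusted p = 0.346). Of the 7 genes, the targeted gene and Tlr12 kept their call with any 1 animal left out, but that of Tlr12 ended in the RPKM tables, with quantile normalization and in females or males alone. The count ran from 2 (without WT-8322) to 103 (39 up, 64 down, without HET-8304). With median centring 26 genes were called, 22 up and 4 down. With a sex term all 15 lists kept their call, and 12 did with any 1 animal left out. That of phagocytic receptors ended without WT-8326, HOM-8282 or HOM-8287, without a filter on low values, and with quantile normalization or array weights. That of T and NK cells ended without WT-8326 and with array weights, and that of astrocytes without WT-8322. The cell cycle call ended at a mean of at least 5 TPM and in the RPKM tables. The lowest and highest means with 1 animal left out were 0.10 and 0.35 for T and NK cells, 0.069 and 0.23 for border-associated macrophages, -0.019 and 0.050 for phagocytic receptors and 0.14 and 0.28 for MHC class II, the lowest without HOM-8285 and the highest without HOM-8286. They were 0.0068 (without WT-8326) and 0.044 for oxidative phosphorylation, -0.0079 (without WT-8325) and 0.080 for cell cycle and 0.081 and 0.33 (without HOM-8285) for immediate early genes. In males alone the calls of cell cycle, immediate early genes, astrocytes and endothelial cells ended, and in females alone those of MHC class I, phagocytic receptors and T and NK cells.

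The heterozygous against wild-type comparison at 3 months asked what loss of 1 copy does. Mars, the methionyl-tRNA synthetase of the cytosol, fell from 76.4 ± 7.52 to 52.2 ± 2.16 TPM (SD, n = 4, log2 change -0.54, SE 0.079, adjusted p = 0.0362). The predicted gene Gm20594 rose from 578 ± 64.4 to 2754 ± 1450.2 TPM, with a log2 change of 2.11 (SE 0.28, adjusted p = 0.0159) and is not listed in the RPKM table. Fbxo21, an F-box protein, and Zfp873, a zinc finger protein, were listed at or near 0 in heterozygotes against 4.87 ± 1.33 and 2.58 ± 0.595 TPM in wild types. Fbxo21 was at 1.66e-07 TPM in HET-8303 and at 0 in the other 3, and Zfp873 was at 2.98e-04 TPM in HET-8309 and between 0 and 8.28e-09 in the others. With the targeted gene, limma called 5 of 11587 genes, 1 higher and 4 lower. In the RPKM tables Fbxo21 and Zfp873 differed by -0.039 and -0.035 on the log2 scale and were not called, and the targeted gene was the 1 gene called there.

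Neuron markers were higher in heterozygotes at 3 months by a mean log2 of 0.90 (adjusted p = 8.32e-10, 0.421 with an estimated correlation), with 0 members called over all genes and 4 of 8 adjusted over the list alone. Heterozygote HET-8304 stood apart in this list, with a score of 2.03 where the other 3 lay from 0.439 to 0.617. Its oligodendrocyte score was 1.46 where the others lay from 0.0433 to 0.220, and the oligodendrocyte list was higher by 0.46 with it (adjusted p = 1.53e-04, 0.444 with an estimated correlation) and by 0.13 without it, when it was not called. Astrocyte markers were higher by 0.34 (adjusted p = 1.75e-06, 0.431 with an estimated correlation). Neutrophil markers were higher by 0.72 (adjusted p = 5.50e-08, 0.431 with an estimated correlation) and monocyte markers by 0.20 (adjusted p = 0.00142, 0.431 with an estimated correlation). Border-associated macrophage markers rose by 0.31 (adjusted p = 8.32e-10, 0.421 with an estimated correlation), with 4 of 14 called over the list alone and Cbr2 at 157 ± 18.1 against 108 ± 9.07 TPM (adjusted p = 0.0517). Oxidative phosphorylation rose by 0.11 (adjusted p = 8.38e-11, 0.431 with an estimated correlation) and ribosomal proteins by 0.058 (adjusted p = 1.13e-14, 0.431 with an estimated correlation). Cholesterol synthesis rose by 0.044 (adjusted p = 0.00235, 0.431 with an estimated correlation), and the unfolded protein response by 0.066 (adjusted p = 0.00111, 0.431 with an estimated correlation), with Manf at 82.3 ± 5.75 against 67.0 ± 3.83 TPM. Without HET-8304 the means were 0.52 for neurons, 0.099 for astrocytes, 0.025 for oxidative phosphorylation, 0.019 for ribosomal proteins and 0.012 for cholesterol synthesis, and these lists stayed called. With any 1 animal left out the means ran from 0.43 (without HET-8309) to 0.98 for neutrophils, from 0.097 (without WT-8326) to 0.32 for monocytes and from 0.033 (without HET-8303) to 0.096 for the unfolded protein response. The cholesterol call ended without a filter on low values and in males alone, and the monocyte call with median centring or array weights. The homeostatic list was not called (mean -0.067, adjusted p = 0.837). All 4 heterozygotes were male against 1 of 4 wild types, and with a sex term 3 genes and 8 of these 10 lists were called, without cholesterol synthesis and monocytes. The gene count ran from 3 (without WT-8322) to 467 (without HET-8309) with 1 animal left out.

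Between homozygotes and heterozygotes at 3 months, the lists for antigen presentation and disease-associated microglia were higher in homozygotes and those for astrocytes, oligodendrocytes, neurons and vessels were lower. MHC class I genes rose by a mean of 0.21 (adjusted p = 3.90e-07, 0.201 with an estimated correlation) and MHC class II genes by 0.29 (adjusted p = 1.40e-05, 0.201 with an estimated correlation), each with 5 members called when adjusted over the list alone. Cd74, the invariant chain of MHC class II, stood at 1549 ± 313 against 1034 ± 92.3 TPM (SD, n = 4, adjusted p = 0.257). The disease-associated list rose by 0.18 (adjusted p = 2.05e-06, 0.201 with an estimated correlation), with 6 members over the list alone and Cst7, a cystatin, at 28.0 ± 3.49 against 17.2 ± 0.796 TPM (adjusted p = 0.0811). Astrocyte markers changed by a mean log2 change of -0.84 (adjusted p = 6.82e-15, 0.201 with an estimated correlation, 12 of 13 over the list alone). Neuron markers changed by -0.96 (adjusted p = 8.67e-09, 0.201 with an estimated correlation, 5 of 8 over the list alone). Endothelial and mural markers changed by -0.94 (adjusted p = 2.05e-08, 0.339 with an estimated correlation). Oligodendrocyte markers changed by -0.55 (adjusted p = 7.82e-04, 0.455 with an estimated correlation) and choroid plexus markers by -0.66 (adjusted p = 0.00121, 0.455 with an estimated correlation). Without HET-8304, which stood apart in the oligodendrocyte and neuron lists, the oligodendrocyte and choroid plexus lists were not called (means -0.21 and -0.20), and the means were -0.60 for astrocytes, -0.58 for neurons and -0.53 for endothelial and mural cells, which stayed called. The oligodendrocyte call also ended in males alone and the choroid plexus call with array weights.

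The ribosomal list was also higher in homozygotes than in heterozygotes (mean 0.16, adjusted p = 4.77e-16, 0.339 with an estimated correlation). Higher too were T and NK cell markers (0.50, adjusted p = 1.05e-04, 0.218 with an estimated correlation) and monocytes (0.39, adjusted p = 0.00121, 0.382 with an estimated correlation). So were cell cycle (0.11, adjusted p = 2.68e-04, 0.339 with an estimated correlation), NF-kB targets (0.18, adjusted p = 5.82e-04, 0.455 with an estimated correlation) and immediate early genes (0.27, adjusted p = 4.35e-04, 0.561 with an estimated correlation). Lower were cholesterol synthesis (-0.15, adjusted p = 6.77e-05, 0.234 with an estimated correlation) and oxidative phosphorylation (-0.086, adjusted p = 0.00121, 0.643 with an estimated correlation). Also lower were the unfolded protein response (-0.079, adjusted p = 0.0352, 0.474 with an estimated correlation) and border-associated macrophages (-0.16, adjusted p = 0.0180, 0.561 with an estimated correlation). The genes called by limma were the targeted gene, Fbxo21 and Zfp873, 3 of 11587, and the last 2 are those listed near 0 in heterozygotes. Without HET-8304 the calls of NF-kB targets, immediate early genes and oxidative phosphorylation ended, with means of -0.022, -0.097 and 0.0018. The unfolded protein call ended without HET-8302, HET-8303, HET-8304 or HOM-8285, that of border-associated macrophages without HET-8303 or HOM-8286 and that of monocytes without HOM-8282. The means ran from -0.11 to -0.046 for unfolded protein, from -0.25 to -0.063 for border-associated macrophages, from 0.20 to 0.54 for monocytes and from 0.070 to 0.16 for cell cycle. Array weights ended the calls of NF-kB targets and oxidative phosphorylation, and a sex term those of cell cycle and border-associated macrophages, which left 16 of 18 lists. The cell cycle call also ended at a mean of at least 5 TPM, those of the unfolded protein response and border-associated macrophages without a filter on low values, and in males alone those of cell cycle, immediate early genes and border-associated macrophages. Without HET-8309 the gene count was 66, and 13 without HET-8304. With median centring 5 genes were called, 4 up and 1 down.

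**Figure D2:**
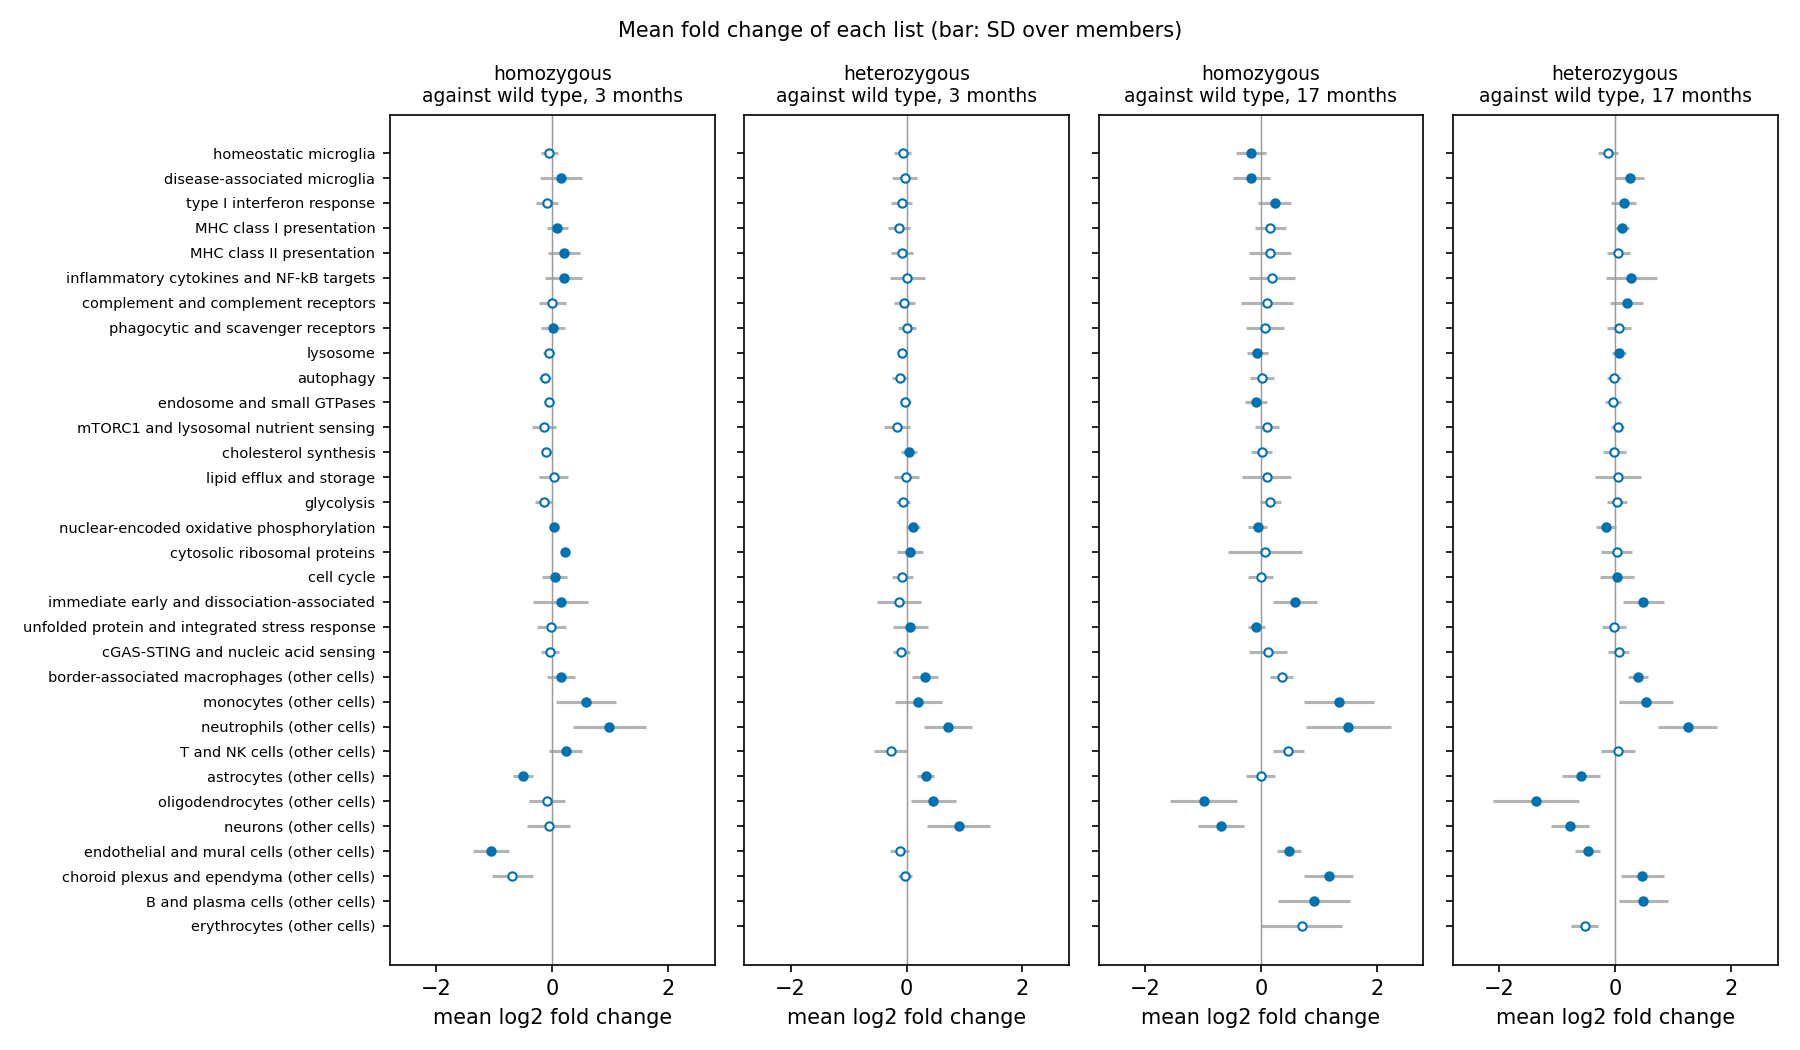
Mean log2 change of each gene list between mutants and wild types of the same age, with bars for the SD over members and filled points where the adjusted p with the preset correlation was under 0.05. No point would be filled with an estimated correlation.

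The homozygous against wild-type comparison at 17 months asked what loss of both copies does with age. Gpr34, a receptor for lysophosphatidylserine and a marker of homeostatic microglia, fell from 653 ± 86.2 to 369 ± 57.5 TPM (SD, n = 4, log2 change -0.83, SE 0.14, adjusted p = 0.0349). Nr4a1, a nuclear receptor induced early after stimulation, rose from 69.0 ± 12.7 to 209 ± 104 TPM (log2 change 1.49, adjusted p = 0.0468), with 363 TPM in HOM-7899 and from 142 to 174 in the others. Zfp36, which promotes decay of cytokine mRNA, rose from 1460 ± 193 to 2389 ± 268 TPM (log2 change 0.71, adjusted p = 0.0409). Rab5a, a GTPase of early endosomes, fell from 52.4 ± 4.97 to 37.2 ± 3.60 TPM (adjusted p = 0.0468). Vtn and Pdgfrb, which mark mural cells, rose with log2 changes of 0.93 and 0.57 (adjusted p = 0.0440 and 0.0459). Among 84 called genes of 11792, 55 were higher and 29 lower, and each separated the 4 homozygotes from the 4 wild types. The largest rises were in Slfn4 (2.12), Cox8b (2.02), 1500015O10Rik (1.73), Igfbp2 (1.63), Ccdc153 (1.59), Nr4a1, Sostdc1 (1.35), Insl3 (1.32), Odf3b (1.28) and Msx1 (1.20). The largest falls besides the targeted gene were in Ermn (-1.41), Hltf (-1.32), Lpar1 (-1.31), Pkp4 (-1.27), Trp53inp2 (-1.17), Tmem88b (-1.13), Adamts4 (-1.12), Svip (-0.93), Tmed5 (-0.89) and Dynlt1b (-0.88). Ermn is an oligodendrocyte protein and Ccdc153 is in the choroid plexus list. RNA of other cells was not excluded for these genes.

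By list, immediate early and dissociation-associated genes rose at 17 months in all 26 members, by a mean of 0.59 (adjusted p = 6.84e-09, 0.580 with an estimated correlation), with 2 called over all genes and 18 adjusted over the list alone. The homeostatic list fell, with a mean of -0.17 (adjusted p = 0.00130, 0.894 with an estimated correlation) and Gpr34 as its 1 called member, also when adjusted over the list alone. The disease-associated list fell, with a mean of -0.17 (adjusted p = 7.51e-05, 0.772 with an estimated correlation) and 0 members called either way. The lysosome list changed by a mean of -0.061 (adjusted p = 0.00724, 0.918 with an estimated correlation) and the endosome list by -0.088 (adjusted p = 0.00556, 0.918 with an estimated correlation). Oxidative phosphorylation changed by -0.056 (adjusted p = 0.0257, 0.918 with an estimated correlation) and the unfolded protein response by -0.079 (adjusted p = 0.0283, 0.918 with an estimated correlation). Interferon response genes rose by 0.24 (adjusted p = 0.0226, 0.918 with an estimated correlation), with Ifitm3 at 502 ± 289 against 253 ± 22.9 TPM (adjusted p = 0.133). The interferon call ended without WT-7783, WT-7785, HOM-7835 or HOM-7899, in the RPKM tables, with only the 2 groups in the fit and with array weights. The oxidative phosphorylation call ended without WT-7783, WT-7943, HOM-7835 or HOM-7893, in the RPKM tables, with quantile normalization and with a sex term, when its mean was 0.036. The unfolded protein call ended without WT-7782, WT-7785 or HOM-7893, at a mean of at least 5 TPM, with quantile normalization and with a sex term. The lysosome call ended without WT-7782, and quantile normalization ended it and the homeostatic call. With 1 animal left out the means ran from -0.26 to -0.078 (without HOM-7893) for disease-associated genes, from -0.25 to -0.099 (without HOM-7901) for homeostatic genes and from 0.12 (without HOM-7899) to 0.37 for interferon. They ran from -0.12 to -0.0033 (without WT-7782) for lysosome, from -0.14 to -0.057 for endosome, from -0.11 to -0.0072 for oxidative phosphorylation and from -0.13 to -0.025 for unfolded protein. In males alone the disease-associated, lysosome, oxidative phosphorylation and immediate early calls ended, and in females alone those of endosome, oxidative phosphorylation and unfolded protein. The ribosomal list was not called (mean 0.066, median -0.045, adjusted p = 0.0607).

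Markers of other cells moved in both directions in aged homozygotes. Oligodendrocyte markers changed by a mean of -0.99 (adjusted p = 1.32e-09, 0.407 with an estimated correlation), with 1 called over all genes and 6 of 10 adjusted over the list alone. Neuron markers changed by -0.69 (adjusted p = 1.23e-04, 0.615 with an estimated correlation). That call ended with a sex term, where 12 of the 15 lists of this comparison were called, and in males alone, with a mean of 0.10, and the mean ran from -1.02 to -0.44 with 1 animal left out. Of these animals 3 of 4 homozygotes and 1 of 4 wild types were male. Markers of monocytes rose by 1.35 (adjusted p = 4.57e-07, 0.444 with an estimated correlation, 1 called over all genes, which was Nr4a1, and 13 of 14 over the list alone) and those of neutrophils by 1.51 (adjusted p = 3.27e-04, 0.772 with an estimated correlation). Choroid plexus and ependyma markers rose by 1.17 (adjusted p = 8.54e-08, 0.407 with an estimated correlation, 1 and 10 of 10) and endothelial and mural markers by 0.49 (adjusted p = 4.74e-07, 0.407 with an estimated correlation, 3 and 7 of 14). B and plasma cell markers rose by 0.92 (adjusted p = 0.0158, 0.514 with an estimated correlation, 0 and 3 of 7), and that call ended with quantile normalization and in females alone. Of 27 named called entries, in which a gene named under 2 parts of the rule counts once, only that of the targeted gene held with any 1 animal left out, and the gene count ran from 1 (without WT-7783) to 367 (without HET-7796). It was 5 with a sex term, 932 (715 up, 217 down) in the RPKM tables, 633 (278 up, 355 down) with quantile normalization and 609 (204 up, 405 down) with median centring.

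The heterozygous against wild-type comparison at 17 months asked what loss of 1 copy does with age. All called genes were lower, and transcripts of myelin proteins were among them. Mbp and Mobp, which encode structural proteins of myelin, fell by 2.33 and 2.26 on the log2 scale (SE 0.39 and 0.40, n = 4, adjusted p = 0.0344 and 0.0427). Mbp stood at 738 ± 314 TPM in heterozygotes and Mobp at 53.7 ± 25.0 against 249 ± 99.7 in wild types. In all, limma called 28 of 11792 genes, 0 higher and 28 lower. Besides the targeted gene the larger falls included those of Mbp, Mobp, Plekhb1 (-2.24), Bcas1 (-2.23), Scd1 (-1.86), Rcan2 (-1.79), Lpar1 (-1.69), Gpm6b (-1.67) and Trp53inp2 (-1.66), and Scd1 desaturates fatty acids. Oligodendrocyte markers fell in all 10 members by a mean of -1.37 (adjusted p = 3.68e-15, 0.126 with an estimated correlation), with 4 called over all genes and 9 adjusted over the list alone. Neuron markers changed by -0.78 (adjusted p = 9.50e-06, 0.410 with an estimated correlation) and astrocyte markers by -0.59 (adjusted p = 1.03e-06, 0.410 with an estimated correlation). Without WT-7943 these means were -0.53 and -0.35. Endothelial and mural markers changed by -0.48 (adjusted p = 1.01e-10, 0.212 with an estimated correlation, 9 of 14 over the list alone).

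Some immune lists were called higher in aged heterozygotes than in wild types, while MHC class II (mean 0.053, adjusted p = 0.556) and cGAS-STING and nucleic acid sensing (0.059, adjusted p = 0.229) were not called. Immediate early and dissociation-associated genes rose by 0.48 (adjusted p = 4.22e-14, 0.405 with an estimated correlation, 10 of 26 over the list alone) and inflammatory genes by 0.28 (adjusted p = 3.30e-07, 0.410 with an estimated correlation, 9 of 29 over the list alone), with 0 members of either called over all genes. Cxcl2, a neutrophil attractant, stood at 40.9 ± 21.8 against 14.0 ± 3.98 TPM (SD, n = 4, adjusted p = 0.157). The disease-associated list rose by 0.25 (adjusted p = 1.03e-06, 0.450 with an estimated correlation), with 0 members called either way and Gpnmb at 40.4 ± 6.12 against 24.2 ± 12.3 TPM. Interferon response genes rose by 0.15 (adjusted p = 2.69e-04, 0.747 with an estimated correlation) and MHC class I by 0.11 (adjusted p = 0.00385, 0.674 with an estimated correlation). Complement genes rose by 0.20 (adjusted p = 0.00468, 0.547 with an estimated correlation), lysosome by 0.062 (adjusted p = 0.0130, 0.817 with an estimated correlation) and cell cycle by 0.030 (adjusted p = 0.0492, 0.802 with an estimated correlation). Oxidative phosphorylation changed by a mean of -0.15 (adjusted p = 1.40e-04, 0.450 with an estimated correlation). Higher markers of other cells were those of neutrophils (1.25, adjusted p = 3.30e-07, 0.410 with an estimated correlation) and monocytes (0.54, adjusted p = 4.29e-04, 0.450 with an estimated correlation). Further ones were those of border-associated macrophages (0.39, adjusted p = 1.19e-04, 0.503 with an estimated correlation), B and plasma cells (0.49, adjusted p = 0.00251, 0.405 with an estimated correlation) and choroid plexus (0.47, adjusted p = 2.69e-04, 0.410 with an estimated correlation). The cell cycle call ended without WT-7782, WT-7943, HET-7791 or HOM-7901, with pseudocount 0.1, median centring or array weights, and at a mean of at least 5 TPM, where its mean was -0.11. Leaving out 1 animal also ended the calls of MHC class I (WT-7785), complement (HET-7795), lysosome (WT-7943 or HET-7795), oxidative phosphorylation (HET-7794), monocytes and B cells (HET-7796 for both). Array weights ended the calls of neutrophils, monocytes, B cells and choroid plexus, quantile normalization that of complement and females alone that of MHC class I. The means of neutrophils and B cells ran from 0.73 and 0.24 (without HET-7796) to 1.92 and 0.70 (without HET-7794). Without HET-7795 and without HET-7796 they were 0.17 and 0.63 for border-associated macrophages, 0.14 and 0.41 for inflammatory genes, 0.071 and 0.23 for interferon, 0.055 and 0.18 for MHC class I and 0.091 and 0.30 for complement. Without WT-7943 and without HET-7796 they were -0.0013 and 0.17 for lysosome and -0.050 and 0.16 for cell cycle, and the disease-associated mean ran from 0.16 to 0.32. With a sex term all 18 lists were called. No named gene call of this comparison held with every animal left out in turn, and the count of 28 ran from 0 (without WT-7783, 847 at an unadjusted p under 0.05) to 232 (without WT-7785). It was 0 without a filter on low values (1714 at an unadjusted p under 0.05), 0 with only these 2 groups in the fit (883), 1 with quantile normalization or median centring, and 220 with a sex term.

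Between homozygotes and heterozygotes at 17 months, transcripts of vessel cells were higher in homozygotes and those of disease-associated microglia lower. Ly6c1 and Cldn5, which mark brain endothelium, stood at 201 ± 27.4 against 73.8 ± 16.6 TPM and 117 ± 18.7 against 44.8 ± 13.8 TPM (SD, n = 4, log2 changes 1.45 and 1.40, adjusted p = 0.00134 and 0.00220). Esam and Vtn rose as well, by 1.32 and 1.16. Of the endothelial and mural list 12 of 14 members were called over all genes and 14 adjusted over the list alone, with a mean of 0.96 (adjusted p = 2.47e-21, 0.0517 with an estimated correlation). In the disease-associated list 0 of 30 members were higher, and the list fell with a mean of -0.41 (adjusted p = 7.80e-19, 0.422 with an estimated correlation), with 4 called over all genes and 10 adjusted over the list alone. These 4 were Lpl, a lipoprotein lipase (-1.37, adjusted p = 0.00751), Clec7a, a receptor for beta-glucans (-0.92, adjusted p = 0.0174), Spp1, the cytokine osteopontin (-1.42, adjusted p = 0.0244), and Cd9, a tetraspanin (-0.39, adjusted p = 0.0413). Spp1 stood at 227 ± 78.0 against 580 ± 60.7 TPM. Gpr34 fell from 611 ± 83.8 to 369 ± 57.5 TPM (log2 change -0.73, adjusted p = 0.0138) and Lamp2, a lysosomal membrane protein, from 258 ± 33.5 to 181 ± 29.7 TPM (-0.51, adjusted p = 0.0425).

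The lysosome list was lower in aged homozygotes than in heterozygotes (mean -0.12, adjusted p = 8.42e-08, 0.892 with an estimated correlation, 1 member called over all genes and over the list alone). Lower too were homeostatic genes (-0.043, adjusted p = 0.0300, 0.962 with an estimated correlation), NF-kB targets (-0.089, adjusted p = 0.00142, 0.892 with an estimated correlation) and complement (-0.10, adjusted p = 9.29e-04, 0.892 with an estimated correlation). The same held for endosome genes (-0.051, adjusted p = 0.0260, 0.962 with an estimated correlation), cell cycle (-0.036, adjusted p = 9.86e-04, 0.892 with an estimated correlation) and the unfolded protein response (-0.060, adjusted p = 0.00468, 0.892 with an estimated correlation). The ribosomal list was called down although its mean was 0.040, with a median of -0.011 (adjusted p = 0.0202, 0.962 with an estimated correlation). Its mean was below 0 in the RPKM tables and with median centring, and its test turned upward with quantile normalization (adjusted p = 0.550). Leaving out 1 animal ended the homeostatic call (HET-7791, HET-7794 or HOM-7901) and those of NF-kB targets (HET-7795), endosome (HET-7795 or HOM-7893) and ribosomal proteins (HET-7791, HET-7795, HET-7796, HOM-7835 or HOM-7893). Quantile normalization ended these 4 and those of complement and the unfolded protein response, and the cell cycle call ended at a mean of at least 5 TPM. With 1 animal left out the means ran from -0.19 to 0.051 for homeostatic genes, from -0.22 to 0.054 for NF-kB targets, from -0.20 to 0.0077 for complement, from -0.16 to 0.025 for cell cycle and from -0.18 to 0.0041 for unfolded protein. They ran from -0.12 to -0.00050 for endosome, from -0.23 to -0.069 for lysosome and from 0.011 to 0.080 for ribosomal proteins, and all but the last were lowest without HET-7796. Higher were markers of astrocytes (0.59, adjusted p = 0.00105, 0.892 with an estimated correlation), monocytes (0.81, adjusted p = 0.00468, 0.892 with an estimated correlation) and choroid plexus (0.70, adjusted p = 8.32e-04, 0.892 with an estimated correlation). In all, limma called 219 of 11792 genes, 199 higher and 20 lower, against 195 (131 up, 64 down) with quantile normalization and 247 (153 up, 94 down) with median centring. No heterozygote and 3 homozygotes were male, and 45 genes were called with a sex term, 89 at a mean of at least 5 TPM and from 103 (without HET-7795) to 245 (without HET-7791) with 1 animal left out. Among the named calls those of the targeted gene, Lpl, Ly6c1, Esam, Cldn5 and Vtn held with any 1 animal left out. With a sex term only the targeted gene, Ly6c1 and Esam of the named genes stayed called, and Lpl, Clec7a, Spp1, Cd9, Gpr34, Lamp2, Cldn5 and Vtn did not. In females alone only the targeted gene did. Of the 13 lists 10 were called with a sex term, without monocytes, ribosomal proteins and the unfolded protein response, and these and the endosome call ended in females alone. The monocyte call also ended without HET-7794 and the astrocyte call without HOM-7901, and the lowest means were 0.46 for monocytes and 0.46 for choroid plexus.

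**Figure D3:**
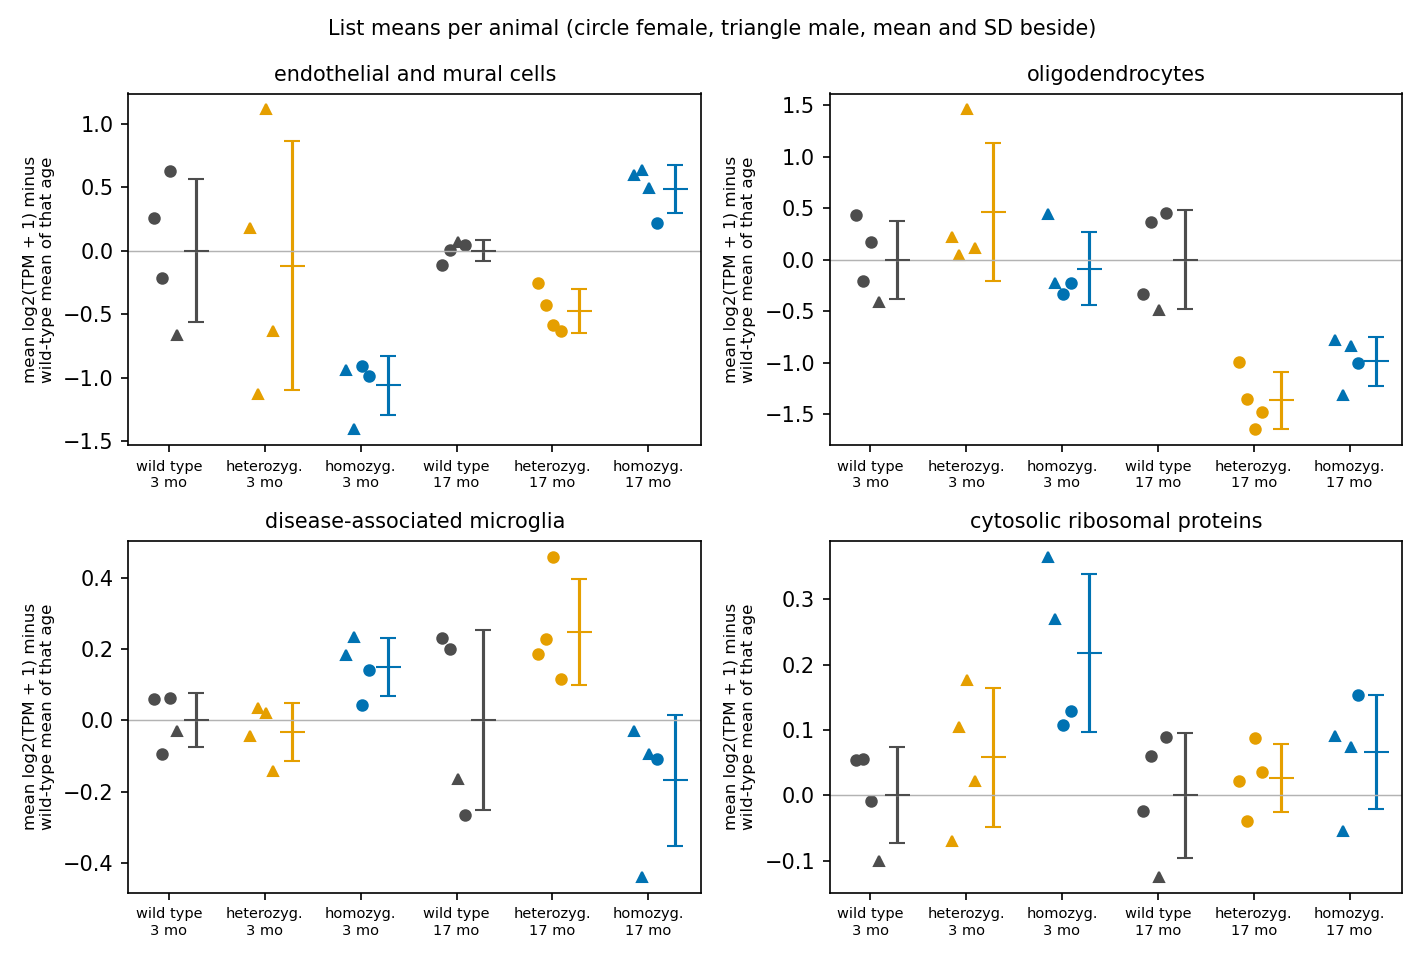
Mean log2(TPM + 1) of 4 gene lists in each animal minus the wild-type mean of that age, with circles for females, triangles for males, and the mean and SD of each group beside them. The endothelial and mural score was lower in all 4 homozygotes than in the wild types at 3 months and higher in all 4 than in the wild types at 17 months.

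Several lists did not pass the test in any of the 6 comparisons. In homozygotes against wild types at 3 and 17 months the means were -0.12 and 0.022 for autophagy (adjusted p = 0.115 and 0.580), -0.15 and 0.11 for mTORC1 and nutrient sensing (adjusted p = 0.570 and 0.488) and -0.044 and 0.12 for cGAS-STING and nucleic acid sensing (adjusted p = 0.923 and 0.725). They were 0.028 and 0.10 for lipid efflux and storage (adjusted p = 0.0851 and 0.912) and -0.15 and 0.16 for glycolysis (adjusted p = 0.307 and 0.0553). When adjusted over the list alone, 6 autophagy genes were lower in homozygotes and 5 in heterozygotes at 3 months, and 0 were called over all genes. Erythrocyte markers, tested at 17 months, had a mean of 0.70 in homozygotes (adjusted p = 0.809) and -0.53 in heterozygotes (adjusted p = 0.349). With an estimated correlation limma's camera called 0 lists in each comparison, with from 2 to 6 lists at an unadjusted p under 0.05.

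Genotype effects were compared between ages over all 24 animals and 11436 genes. In homozygotes 29 genes differed, 23 of them upward with age, and Zdhhc1, a palmitoyltransferase, went from a log2 change of -0.24 at 3 months to 0.52 at 17 months (difference 0.76, SE 0.11, adjusted p = 0.00390). Dock6, Scarf1, Cluh and Fam65a followed with differences of 1.10, 1.10, 0.69 and 0.72 (adjusted p from 0.0348 to 0.0406). In heterozygotes 79 genes differed, 23 upward and 56 downward. Ermn went from 0.55 to -1.59 (difference -2.14, SE 0.31, adjusted p = 0.00794), and Scd1, Mturn, Plekhb1 and Pkp4 differed by -2.60, -1.82, -3.30 and -1.81 (adjusted p = 0.0113 each). Endothelial and mural markers differed by 1.55 in homozygotes (adjusted p = 1.53e-07, 0.596 with an estimated correlation). The disease-associated list differed by -0.32 in homozygotes (adjusted p = 1.99e-11, 0.333 with an estimated correlation) and by 0.28 in heterozygotes (adjusted p = 0.00804, 0.918 with an estimated correlation). Heterozygotes were all male at 3 and all female at 17 months, and a sex term ended that last call. Oligodendrocyte markers differed by -1.83 in heterozygotes (adjusted p = 2.89e-13, 0.140 with an estimated correlation). RNA of such cells was not excluded for the heterozygous genes. The 5 named heterozygous genes and Zdhhc1 kept their call with any 1 animal left out, while the homozygous count ran from 1 (without 3-month WT-8322) to 655 (without 17-month HET-7796). That count split into 54 up and 94 down with quantile normalization and 87 up and 336 down with median centring. Centring gave 21 up and 104 down in heterozygotes.

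Both mutants were compared with the same wild types, which alone makes their changes correlate. At 3 months the correlation across 11586 genes, which are not independent replicates, was 0.402, where simulated unchanged groups against shared controls gave 0.498. With the wild types split between the comparisons it was 0.145 on average over 6 splits, from -0.067 to 0.298. The covariance was 0.0218 against 0.0165 in the simulations. No called gene besides the targeted gene was shared, with 2 and 1 higher and 4 and 3 lower genes and 1.73e-04 and 0.00104 shared genes from independent lists, against 0.11 and 0.36 in simulated lists of the same sizes with shared wild types. At 17 months the correlation across 11791 genes was 0.573 where simulations gave 0.502, and 0.299 with split controls, from 0.119 to 0.364. The covariance was 0.0536 against 0.0238. Of 28 lower genes in homozygotes and 27 in heterozygotes 9 were shared where independent lists give 0.0641 and lists of the same sizes from unchanged groups with shared wild types gave 4 on average and at most 8 in 100 simulations. The 9 were Adamts4, Dusp19, Ermn, Lpar1, Pkp4, Qdpr, Svip, Tmem88b and Trp53inp2. No higher gene was shared, since limma called 55 in homozygotes and 0 in heterozygotes. Leaving out 1 animal moved the correlation from 0.270 (without HET-8303) to 0.585 (without HET-8304) at 3 months and from 0.479 (without HET-7791) to 0.668 (without WT-7785) at 17 months.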

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

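The tests with a sex term, the match of ribosomal genes by length alone and the counts of splits without the targeted gene were chosen after the results were seen. Among 211 groups of 4 animals, 17 held an animal whose gap to the nearest other was large for the range of the group, and chance gives about 1 in 20 such groups, here 10.55.

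Endothelial and mural markers were higher in homozygotes than in heterozygotes at 17 months by 0.96 (SE 0.11). With a sex term the difference was 0.80 (SE 0.12), which argues against sex as the whole cause. With a depth term it was 0.91 (SE 0.12). That term cannot decide, since all homozygous libraries (40.7 to 46.4 M alignments) were deeper than all heterozygous ones (30.6 to 37.1 M). RNA of vascular cells carried through the CD11b sort is a candidate explanation that stays open, and that sort should remove such cells. The 187 other genes called upward had a median correlation with the marker score within genotypes of 0.499, where the remaining genes had 0.192, and Ly6c1 reached 201 TPM in homozygotes and 73.8 in heterozygotes. A difference in the vessels themselves, or in the exact age of the animals, may also contribute and was not tested.

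Most of the 83 genes called besides the targeted gene between homozygotes and wild types at 17 months lost their call with a sex term, which left 1 of them, and 5 genes were called in all. Their median change went from 0.80 to 0.77 and their median SE from 0.148 to 0.169, a ratio of 1.15, so the calls ended with a wider error and not with a smaller change. The ratio of changes with and without the sex term had a median of 0.981 and all 83 kept their direction, and with a depth term it was 0.995, with an SE ratio of 1.30 and 0 of the 83 calls left. Sex cannot be judged, since the 83 were called without its term and separate groups of mixed sex. Nor can depth, since all homozygous libraries (40.7 to 46.4 M) were deeper than all wild-type ones (16.7 to 35.7 M). Other cells were not excluded either, so the origin stays open.

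Ribosomal protein transcripts were higher in homozygotes than in wild types at 3 months by 0.22 (SE 0.072). Genes matched for length and level, though longer (177, median 1830 against 1139.5 bases), changed by 0.0032 (SE 0.018). The 471 matched by length alone (median 1153) changed by -0.027 (SE 0.013), which argues against length alone. With a sex term the difference was 0.20 (SE 0.077), which argues against sex as the whole cause. A depth term (0.43, SE 0.11) cannot decide, since all homozygous libraries were deeper. RNA of blood cells, whose markers were also higher, was not tested as a source. A genotype effect is a hypothesis only, and the call was lost with an estimated correlation.

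The real grouping was set against the other splits of the same 8 animals into 4 and 4, 35 in all, and the counts of splits as large include the real one. At 3 months the share was under 0.05 for homozygotes against wild types (7 genes, highest other 1) and against heterozygotes (3, highest other 1). At 17 months it was under 0.05 for heterozygotes against wild types (28, highest other 6) and homozygotes against heterozygotes (219, highest other 1). Each of these had 1 split as large. These counts hold the targeted gene, which the real grouping separates by design, and without it they were 6, 2, 27 and 218 with the highest others at 1, 1, 6 and 1. The 2 genes left between the mutants at 3 months are Fbxo21 and Zfp873, which were not called in the RPKM tables, so that count does not point to a genotype effect. Chance could not be excluded for heterozygotes against wild types at 3 months (5, highest other 156, with 2 splits as large), and a split calling so many genes points to a structure of these samples other than genotype. It was not excluded for homozygotes against wild types at 17 months (84, highest other 112, 2 splits as large). The larger split, males against females, shared 0 of the 84. Each of the 84 separates groups of mixed sex, so this cannot decide on sex. For the list counts chance could not be excluded in any comparison. At 3 months these were 15 lists in homozygotes against wild types (highest other 17, 4 splits as large), 10 in heterozygotes (highest other 17, 24 splits) and 18 between the mutants (highest other 18, 3 splits). At 17 months they were 15 (highest other 19, 7 splits), 18 (highest other 22, 4 splits) and 13 (highest other 20, 26 splits). For the difference between ages 100 splits were drawn. The share was under 0.05 for homozygotes (29 genes, highest other 2, 1 split as large) and heterozygotes (79, 4 splits as large). In heterozygotes 1 split called 1170 genes, which points to a structure of the samples.

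Single animals stood apart as follows. At 3 months WT-8323 had a phagocytic and scavenger receptor score of -0.0301 where the others lay from 0.00879 to 0.0124. HET-8304 had an oligodendrocyte score of 1.46 (others 0.0433 to 0.220) and a neuron score of 2.03 (others 0.439 to 0.617). HET-8303 had 1.66e-07 TPM of Fbxo21 (others 0) and HET-8309 had 2.98e-04 TPM of Zfp873 (others 0 to 8.28e-09). HOM-8286 had 33.8 M alignments (others 30.6 to 31.0). HOM-8285 had an immediate early score of -0.41 (others 0.315 to 0.334) and an endothelial and mural score of -1.41 (others -0.988 to -0.905). HOM-8282 had an oligodendrocyte score of 0.45 (others -0.330 to -0.229).

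At 17 months WT-7782 had 16.7 M alignments (others 34.5 to 35.7) and WT-7943 a cell cycle score of -0.24 (others 0.0660 to 0.101). HET-7791 had an oxidative phosphorylation score of -0.0746 (others -0.186 to -0.171). HOM-7899 had 46.4 M alignments (others 40.7 to 41.5), 29.2 TPM of Slfn4 (others 6.53 to 10.3) and 363 TPM of Nr4a1 (others 142 to 174). HOM-7835 had 6.80 TPM of Svip (others 5.01 to 5.19) and 22.7 TPM of Tmed5 (others 15.0 to 16.1). HET-7796 was not marked by this rule, which did not cover whole profiles, and yet lay at 51.2 on the first principal component of its age (other animals -19.7 to 17.1). It had 14062 genes above 0 TPM (others at least 15253) and the lowest TPM total. At 3 months HET-8304 lay at -49.1 on that component (others -8.98 to 15.7).

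The change from wild type differed between ages for 10 genes, named by smallest adjusted p. In homozygotes these were Zdhhc1 (0.76), Dock6 (1.10), Scarf1 (1.10), Cluh (0.69) and Fam65a (0.72), and in heterozygotes Ermn (-2.14), Scd1 (-2.60), Mturn (-1.82), Plekhb1 (-3.30) and Pkp4 (-1.81). It differed for 23 lists with the preset correlation and for 0 with an estimated correlation, where the smallest adjusted p was 0.140. The mean differences (17 minus 3 months) in homozygotes were -0.12 for homeostatic genes, -0.32 for disease-associated genes and -0.054 for MHC class II. They were -0.0042 for NF-kB targets, -0.0018 for lysosome, -0.030 for endosome and 0.31 for glycolysis. They were -0.082 for oxidative phosphorylation, -0.15 for ribosomal proteins, -0.047 for cell cycle and -0.069 for the unfolded protein response. They were -0.90 for oligodendrocytes, -0.68 for neurons, 1.55 for endothelial and mural cells and 1.80 for choroid plexus. In heterozygotes they were 0.28 for disease-associated genes, -0.27 for oxidative phosphorylation, -0.032 for ribosomal proteins and 0.61 for immediate early genes. They were -0.90 for astrocytes, -1.83 for oligodendrocytes, -1.74 for neurons and -0.36 for endothelial and mural cells. Heterozygotes were all male at 3 months and all female at 17, so sex may add to their differences, and other cells were not excluded. With a sex term their disease-associated list was not called, and the others were.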

How the results depend on the processing

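Fits on 1 sex and leave-one-out correlations between both mutants were chosen after seeing the data. For the 20 results that answer a comparison, 259 of 408 alternative values stayed within 1.5 times the reported count or within the spread, and 149 did not. For correlations the spread is the SD of the leave-one-out values. For single genes and lists, 6744 of 7838 alternative values kept direction and side of the threshold, 874 lost the call, 162 gained it and 58 changed sign, of which 49 were called in neither fit. The 4 TPM differences of the targeted gene held throughout. Its call by limma in heterozygotes did not, and ended at 3 months with pseudocount 0.1 and in males only. At 17 months it ended without WT-7783, HET-7794 or HET-7796, with pseudocount 0.1, without a filter on low values and with only the 2 groups compared. No paired analysis was possible because the columns carry animal numbers that the labels' replicate numbers cannot be tied to, and the replicate block and the RNA input covariate were not run for that reason. The alignments per library limit the precision of low values and could not be used as weights without counts. Where an arm kept 1 animal of a sex, that animal was assumed to vary like the other groups. A fit with fewer genes or animals changes a count by its construction, and elsewhere the cause was not tested.

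Below, HOM, HET and WT are the genotypes. With pseudocount 0.1 HOM-WT at 17 months called 19 genes and the correlation at 17 months was 0.522. Without a filter on low values HET-WT at 3 months called 10 genes, and at 17 months HOM-WT called 11 and HET-WT 0 (limma, 1714 at an unadjusted p under 0.05). With a mean TPM of at least 5 the 3-month counts were 23 for HOM-WT, 89 for HET-WT and 1 for HOM-HET, and HOM-HET at 17 months called 89. The age difference in HET called 44, and the cell cycle list in HET-WT at 17 months turned to -0.11. In the RPKM tables HET-WT and HOM-HET at 3 months called 1 gene each, at 17 months HOM-WT called 932 and HET-WT 17. The age difference in HOM called 556, and Tmem119 in HET-WT at 3 months turned to 0.069. With quantile normalization the 3-month counts were 2 for HOM-WT and 7 for HOM-HET, the 17-month counts 633 for HOM-WT and 1 for HET-WT. The age differences were 148 in HOM and 132 in HET, and HOM-HET at 17 months had 7 lists. Under it Tmem119 in HET-WT at 3 months turned to 0.025. At 17 months Wdr41 in HOM-WT turned to -0.053 and Smcr8 in HOM-HET to -0.011, and the ribosomal list in HOM-HET, whose test turned upward, stood at 0.056. With median centring the 3-month counts were 26 for HOM-WT and 5 for HOM-HET, the 17-month counts 609 for HOM-WT and 1 for HET-WT, and the age differences 423 in HOM and 125 in HET. Under it Tmem119 turned to 0.11 in HET-WT at 3 months, and at 17 months Wdr41 turned to -0.062 in HOM-WT, Smcr8 to -0.013 and Tmem119 to -0.043 in HOM-HET. It also moved the median of all genes at 3 months from -0.099 to 0.014 in HOM-WT and from -0.089 to 0.021 in HET-WT.

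With only the groups compared in the fit, the 3-month counts were 23, 3 and 5 for HOM-WT, HET-WT and HOM-HET, and at 17 months 211 for HOM-WT and 0 for HET-WT (limma, 883 at an unadjusted p under 0.05). With array weights they were 1836, 3507 and 3074 at 3 months, 1858, 659 and 1136 at 17 months, and 3321 and 3045 for the age differences in HOM and HET. Under weights P2ry12 turned to -0.18 and oxidative phosphorylation to 0.029 in HOM-HET at 3 months, and at 17 months Wdr41 turned to 0.046 in HET-WT and to -0.017 in HOM-HET. With a sex covariate HOM-WT and HET-WT called 2 and 3 genes at 3 months, the 17-month counts were 5, 220 and 45, and the age differences 58 in HOM and 194 in HET. Under it, at 3 months, Tmem119 turned to 0.10 and P2ry12 to -0.092 in HET-WT and Cx3cr1 to 0.012 in HOM-HET. At 17 months Wdr41 turned to -0.021 and oxidative phosphorylation to 0.036 in HOM-WT, and in HOM-HET Smcr8 turned to -0.096, Tmem119 to -0.15 and the ribosomal list, upward in its test, stood at 0.15. Females only gave 3, 116 and 2 genes at 17 months, and in HOM-HET Smcr8 turned to -0.15, Tmem119 to -0.20 and the ribosomal list, upward in its test, stood at 0.13. Males only gave 1, 0 (limma, 531 at an unadjusted p under 0.05) and 1 genes at 3 months and 5 for HOM-WT at 17 months. Under it, at 3 months, P2ry12 turned to -0.20 in HOM-WT and to -0.26 in HET-WT and Tmem119 to 0.086 in HET-WT. In HOM-WT at 17 months Wdr41 turned to -0.049, Ndufb9 to 0.20, Cox6a1 to 0.16, Gap43 to 0.32, oxidative phosphorylation to 0.074 and the neuron list to 0.10. With an estimated correlation camera called 0 lists in HOM-WT, HET-WT and HOM-HET at 3 months (6, 2 and 6 at an unadjusted p under 0.05) and 0, 0 and 0 at 17 months (3, 3 and 2). With the wild types split the correlation was 0.145 at 3 months and 0.299 at 17 months.

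With 1 animal left out in turn, the lowest and highest values were as follows. HOM-WT at 3 months ran from 2 to 103 genes and moved in all 12 fits, with 103 without HET-8304, 3 without WT-8323, HOM-8285 or HOM-8286, and 2 in each of the others. HET-WT at 3 months ran from 3 (without WT-8322, WT-8325 or HET-8302) to 467 (without HET-8309), with 22 without HET-8304. HOM-HET at 3 months ran from 3 to 66 (without HET-8309), with 13 without HET-8304 and 6 without WT-8322. HOM-WT at 17 months ran from 1 (without WT-7783, WT-7943, HOM-7893 or HOM-7899) to 367 (without HET-7796), with 2 without WT-7782 or HOM-7901, 38 without HET-7791, 133 without WT-7785 and 159 without HOM-7835. HET-WT at 17 months ran from 0 (limma, without WT-7783, 847 at an unadjusted p under 0.05, or HET-7794, 1325) to 232 (without WT-7785). It was 1 without HET-7796, 2 without HET-7795, 10 without WT-7943 or HOM-7901, 11 without HOM-7899, 15 without HOM-7835 and 18 without HET-7791. HOM-HET at 17 months ran from 103 (without HET-7795) to 245, with 104 without HOM-7899 and 111 without HOM-7893. The age difference in HOM ran from 1 to 655 (without HET-7796) and moved in 22 of 24 fits. It was 1 without WT-8322, WT-8323, WT-8325, WT-7785, WT-7943, HET-8302, HET-7791, HOM-8282, HOM-8286, HOM-8287 or HOM-7899, and 2 without HOM-8285 or HOM-7893. It was 4 without WT-7783, 11 without HOM-7901, 101 without HET-8309, 196 without HET-7794, 203 without WT-8326, 221 without HET-8303, 358 without WT-7782 and 467 without HET-8304. The age difference in HET ran from 19 (without WT-7943) to 332 (without HET-7796) and moved in 15 fits. It was 20 without WT-8323 or HET-7795, 22 without WT-7783, 32 without WT-8325, 37 without HET-8304, 39 without HET-8302, 48 without HET-7791, 49 without HET-8303, 51 without WT-8322, 52 without WT-8326, 140 without WT-7782, 218 without HET-8309 and 248 without WT-7785. List counts ran from 13 to 16, 10 to 12 and 13 to 19 at 3 months and from 14 to 18, 16 to 20 and 10 to 17 at 17 months. The correlation ran from 0.270 (without HET-8303, and also without HET-8309) to 0.585 (without HET-8304) at 3 months, with 0.504 without WT-8326, and from 0.479 (without HET-7791) to 0.668 (without WT-7785) at 17 months.

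Signs of values near 0 turned in some of these fits, and some are given here with the range over all of them. The report gives further list means that crossed 0. At 3 months Tmem119 in HET-WT ran from -0.054 to 0.048 and was above 0 without WT-8323 (0.035), WT-8325 (0.020), HET-8303 (0.0039) or HET-8309 (0.048). P2ry12 in HET-WT ran from -0.035 (without HET-8303) to 0.21. In HOM-HET P2ry12 ran from -0.081 (without HET-8304) to 0.15, with -0.068 without HET-8309 and -0.069 without HOM-8285. There Cx3cr1 ran from -0.057 to 0.043 (without HET-8303), with 0.010 without HET-8302. Without HET-8304 the lowest values there were -0.030 for Smcr8 (highest 0.26), -0.052 for Nr4a1 (highest 1.25) and -0.11 for Egr2 (highest 1.26). Oxidative phosphorylation ran from -0.12 to 0.0018 (without HET-8304).

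At 17 months Wdr41 in HOM-WT ran from -0.052 (without WT-7943) to 0.063, with -0.0029 without WT-7783. Without HET-7796 the highest values in HET-WT were 0.12 for Wdr41 (lowest -0.28) and 0.026 for Cx3cr1 (lowest -0.21). Without it the lowest values in HOM-HET were -0.027 for Smcr8 (highest 0.18), -0.11 for Wdr41 (highest 0.29) and -0.12 for Tmem119 (highest 0.14). Tmem119 was also below 0 without HOM-7835 (-0.075). Cx3cr1 in HOM-HET ran from -0.23 to 0.014 (without HET-7794), with 0.00037 without HOM-7901.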

Other observations

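The tables of the 2 ages were made separately, so wild-type levels at 17 and 3 months are set side by side and the difference was not tested. Disease-associated genes were at higher levels in the older wild types. In 20 of 30 such genes all 4 animals of 17 months lay above all 4 of 3 months and in 0 all lay below, where chance gives 1.43% in each direction. Apoe, a lipid carrier, stood at 4700 ± 328 TPM at 3 months and 11994 ± 3200 TPM at 17 months (SD, n = 4), and Spp1 at 15.0 ± 3.93 and 422 ± 165 TPM. Cst7 stood at 22.3 ± 3.34 and 143 ± 31.8 TPM, and Ch25h, which makes 25-hydroxycholesterol, at 1.86 ± 0.429 and 20.6 ± 10.4 TPM.

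Markers of other cells were higher as well, with all older wild types above the younger ones in 5 of 10 oligodendrocyte and 3 of 8 neuron genes and below in 0 (median differences 1.31 and 1.33, against 0.82 for disease-associated genes). A difference in the cells collected at the 2 ages was therefore not excluded.

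In 15 of 20 homeostatic genes all older wild types lay below the younger ones and in 0 above, with Csf1r, the receptor microglia need to survive, at 6536 ± 412 and 3713 ± 553 TPM and Cx3cr1 at 3523 ± 236 and 2299 ± 318 TPM. Of 50 ribosomal genes, 46 lay above at 17 months, as did 21 of 40 for oxidative phosphorylation and 10 of 20 for MHC class I. In autophagy 22 of 33 lay below and in nucleic acid sensing 16 of 24. Over all 11436 genes the median difference was -0.36, with 786 above and 5974 below, so a lower level was the usual case.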
